A study of Homo sapiens with 2 samples.

How the data were processed

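Gene expression was measured in total RNA of Hep3B cells, labelled with biotin and hybridised to an Affymetrix whole-transcript array. The design had 1 array of the SOX4 knockout line and 1 of the parental line, as the genotype labels give them. Per the labels' protocols the cells were taken for RNA extraction near confluence, the RNA was treated with DNase on a column, and the knockout line alone was kept in puromycin. Genotype, puromycin, passage through selection and the array itself therefore cannot be separated.

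The deposited values are on a log2 scale, made by the authors with RMA and Transcriptome Analysis Console per the submitters' processing notes, whose versions are not given in the sources used here. RMA corrects background, normalizes between arrays and summarizes probes per transcript cluster. The base of the log is not stated by a label, and base 2 is what RMA writes. The values ran from 2.13 to 19.80 in the knockout array and from 2.12 to 19.82 in the parental array, with 870 and 838 transcript clusters above 16, the number of bits of a scanner. The scale thus seems to have been altered beyond plain RMA in a way that is not given, and folds are those of the deposited scale. The quartiles were 3.20 and 5.23 in the knockout array and 3.23 and 5.24 in the parental array. The labels name the Human Transcriptome Array 2.0, but the number and form of the transcript cluster identifiers are not those usual for that array, so the array design is not settled here. Scanner files were not used here, no detection calls were at hand, and no bound for signals near background could be set.

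Names came from the platform annotation supplied with the data, which lists 37295 of the 135750 transcript clusters, all found in the value table. It gives 1 gene symbol to 36176 clusters, several to 1119 and none to 98455, and no gene was named from a cluster with several. RefSeq entries of assembly GRCh38.p14 matched 25516 of the clusters with 1 symbol through Entrez identifiers and changed 0 symbols. That assembly served only for names, chromosomes and the order of genes, since the build behind the values is not given in the sources used here. Each gene was represented by its cluster with the highest mean over both arrays, which left 33616 genes, of which 1576 had more than 1 cluster. The level filter kept genes whose higher value exceeded the median of that value over all genes, 4.78, which left 16808 genes, 11115 of them protein-coding.

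With 1 array per genotype no test was run. Genes at least 2-fold apart (1 on the log2 scale) were counted by a fixed rule of size. The genes named were SOX4, CXCL12, CXCR4, ACKR3, SOX11 and SOX12, the 15 highest and 15 lowest above the filter after leaving out small RNAs, receptor segments, uncharacterised symbols and antisense, intronic or overlapping transcripts by their symbols, and up to 4 members per gene list among those above the level filter, namely the 2 largest differences and the highest and lowest member. That made 139 genes. Y-linked genes and XIST were left out of the ranking too, in addition to the rule as written. Any gene outside the rule is said to have been picked after its values were seen, or belongs to a non-coding class, a block's ends, or a comparison made later. NQO1 and HMOX1 were also picked after their values were seen.

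The median difference of each of 46 gene lists and 7 marker lists was set against 10000 random lists of the same size, matched on mean level in 20 bins, and called above or below when outside the central 95%. Draws within a bin were made with replacement where few genes came from it, and without otherwise. They came from all named genes, non-coding ones included, while list members mostly code for proteins. Above the filter, 923 and 478 of 11115 protein-coding genes were 2-fold higher and lower, against 1093 and 612 of all 16808. The random ranges may thus be too narrow for these lists. The percentile describes these arrays and is not a p-value over cultures. List medians cover all measured members, also those under the level filter, unless said otherwise. Lists share members, so their calls are not independent. The value of 1 gene list is not reported here. Chromosome medians were set against random sets in the same way, with 10000 sets, or 2000 for chromosomes with over 300 genes and in the alternatives, where 10000 had been planned. Runs of 25 neighbouring genes were compared with 100 shuffled orders within level bins. The rule for named genes, the lists, the counts and the alternatives were fixed before the data were examined, apart from those said to be added later.

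The counting and the random lists were tested on simulated data for the knockout against parental comparison, with 33616 genes and a noise SD of 0.302 taken from the genes below the filter. Of 200 changed genes, those changed by 1.5 log2 were recovered in 98% and those changed by 3 log2 in 100%, and 23 unchanged genes passed 2-fold. That noise is a spread across dim genes and not a spread of replicates, so the true error of bright genes is unknown. Of 1000 unchanged lists, 5.4% fell outside the central 95%. The noise was drawn independently per gene, so this checks the procedure and not lists whose genes vary together. A smaller run done earlier had put a larger share outside, and the simulation was enlarged and its accepted limit made stricter after that was seen.

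Alternatives were the mean of all clusters of a gene, centring each array on its median, quantile normalization, removal of a loess trend of the difference on level (span 0.3), other filters and fold thresholds, list means in place of medians, members above the filter only, no matching on level, and all genes with a position. Leaving out a replicate could not be run with 1 array per genotype, and another background correction could not be run without scanner files. Lists of members whose mean over both arrays exceeded the filter, lists and counts without chromosome 21 and without blocks of neighbouring genes, NRF2 targets without aldo-keto reductases, and families of symbols were added after seeing the data. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.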

Results

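Total RNA of Hep3B cells, an established human hepatocellular carcinoma line, was profiled on an Affymetrix whole-transcript array. A SOX4 knockout line made with CRISPR/Cas9 was set beside the parental line, with 1 array for each. SOX4 is a transcription factor of the SOX family that acts in development and is often raised in tumours. The knockout cells were kept in puromycin and the parental cells were not. With 1 array per genotype the differences have no replicate check, so no test, standard error or p-value is given, and every "higher" or "lower" describes these 2 arrays. The number of arrays limits the precision of each value. Values are the deposited log2 values, and differences are knockout minus parental. The median over all 135750 transcript clusters was 3.80 in the knockout array and 3.83 in the parental array. The highest values were 19.80 and 19.82, above what log2 of a 16-bit scanner signal can reach, so the scale was probably altered before deposit and fold values hold on the deposited scale only.

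SOX4, the targeted gene, was lower in the knockout array. Its transcript cluster, TC0600007158.hg.1 on chromosome 6, stood at 12.44 in the knockout array and at 13.14 in the parental array, a difference of -0.70 or 1.62-fold. Of 1017 genes within 0.5 log2 of its mean level, 85 were lower by more, and the SD of the difference among those genes was 0.68. An edit that leaves the transcript in place is not seen by such probes, so the value neither shows nor excludes the loss of SOX4 protein. The 15 measured neighbours of SOX4 on its chromosome arm had a median difference of 0.08, inside the range of random lists. They ran from 0.67 for the acyltransferase gene MBOAT1 to -0.56 for the non-coding RNA gene CASC15. Among other SOX family genes, SOX5 stood at -0.87, SOX9 at 0.64 and SOX12 at 0.62, while SOX11 lay under the level filter in both arrays. The 16 measured SOX genes had a median difference of 0.00.

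The comparison asks which transcripts differ between SOX4 knockout and parental Hep3B cells. The genes that stood highest against the parental array were led by aldo-keto reductases, enzymes that reduce carbonyl compounds and steroids. AKR1B15 stood at 14.12 against 4.95, AKR1B10 at 12.67 against 3.71 and AKR1C2 at 12.44 against 5.89. The neuronal membrane protein gene SLITRK6 was 8.67 higher, the actin-associated LIMCH1 7.37 higher, the membrane protein gene TM4SF1 6.30 higher and ELMO1, which acts in Rac activation, 6.12 higher. TIMP1, an inhibitor of matrix metalloproteinases, was 5.95 higher, the phosphatase subunit PPP2R2C 5.95, the cell cycle inhibitor CDKN1A 5.52 and BAAT, which joins bile acids to amino acids, 5.34. AKR1C1 at 5.15, AKR1C3 at 5.01, the pseudogene AKR1B10P1 at 8.21 against 3.20, and the lipase gene MGLL at 4.97 complete the 15 highest. AKR1B10, AKR1B15 and AKR1B10P1 are close in sequence, as are the AKR1C genes, and probes may share signal among them, so how the difference splits within either group is uncertain. In 8 of the 15 highest genes the parental value was at or below the level filter of 4.78.

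With non-coding symbols left out of the ranking, the lowest genes in the knockout array included AFP, the fetal serum protein used as a marker of liver cancer, at 9.73 against 15.50, and DLK1, a membrane protein of liver progenitors, at 4.80 against 10.63. CYP2B6, a drug-metabolising cytochrome, was lowest of the ranked genes with 5.98 against 11.87, a difference of -5.89. The carbonyl reductase gene CBR1 stood at -5.15, the motor protein gene MYO10 at -4.79, CER1, a secreted antagonist of BMP and Nodal, at -4.33, and CPS1, the entry enzyme of the urea cycle, at -4.21. The actin-bundling FSCN1 was at -4.04, PBDC1 at -3.92, the nuclear receptor ESRRG at -3.73, ZNF676 at -3.69, FAM3B at -3.60, the membrane protease MMP16 at -3.26, IGDCC3 at -3.20 and ZNF730 at -3.15. Of these 15 genes, 5 (CBR1, CER1, FAM3B, ZNF676 and ZNF730) lie on chromosome 21 or in a run of neighbouring genes that were lower together. In 7 of the 15 lowest genes the knockout value was at or below the level filter, so those differences, like the ones with a dim parental value above, rest on signals not shown to exceed background.

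Among 16808 genes above the level filter, 1093 (6.50%) were at least 2-fold higher in the knockout array and 612 (3.64%) at least 2-fold lower. The protein-coding genes made up 923 and 478 of these. At 4-fold or more, 226 were higher and 80 lower, and at 16-fold or more 38 and 9. Values of the arrays correlated across all 33616 genes with r = 0.988 and across those above the filter with r = 0.977; genes are not independent replicates. The SD of the difference was 0.70 above the filter and 0.30 below it, where 35 genes were 2-fold higher and 40 lower.

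**Figure D1:**
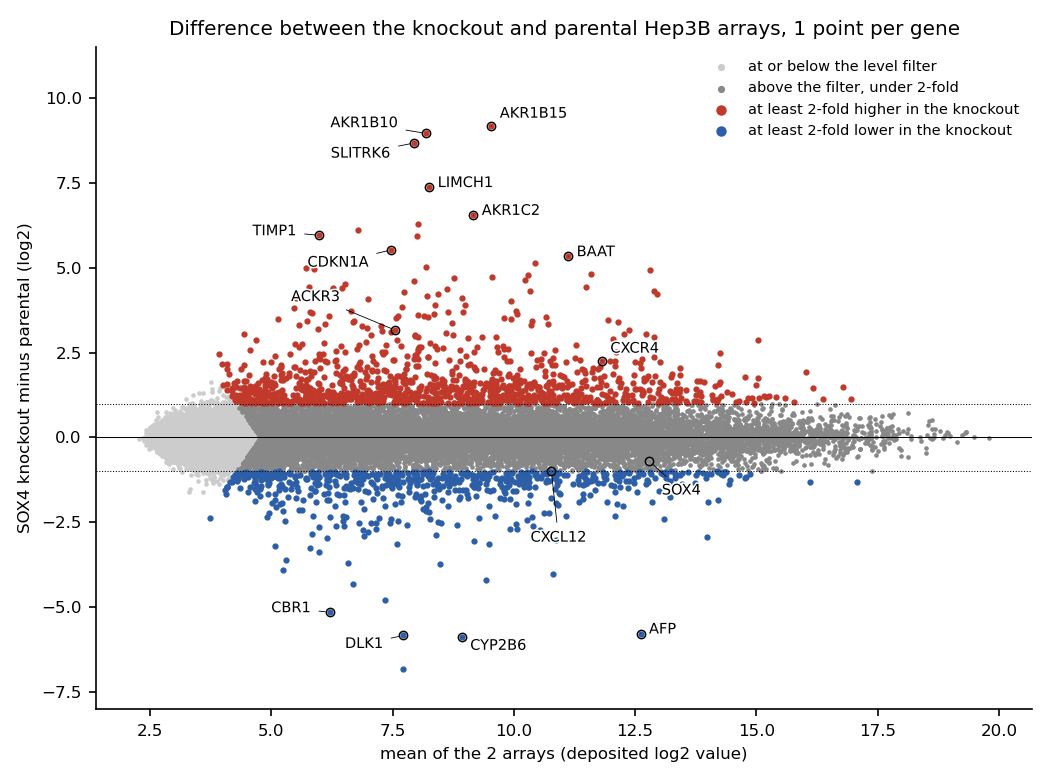
Each point is a gene, with its mean deposited log2 value over both arrays on the horizontal axis and its difference, SOX4 knockout minus parental, on the vertical axis; dotted lines mark 2-fold. Red points are the 1093 genes at least 2-fold higher and blue points the 612 at least 2-fold lower above the level filter, with AKR1B15 at 9.17 and CYP2B6 at -5.89.

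Genes of the NRF2 program, which code for antioxidant, NADPH-forming and detoxifying enzymes, were higher together in the knockout array. All 19 measured members lay above the level filter; 11 were at least 2-fold higher and 1 at least 2-fold lower. Besides AKR1B10 and the AKR1C genes, the quinone reductase gene NQO1 was 3.05 higher. The cystine transporter gene SLC7A11, also counted among ATF4 targets, stood at -1.13, and the heme oxygenase gene HMOX1 at -0.11. The list's median difference of 1.16 lay above all 10000 random lists of like level, whose central 95% ran from -0.20 to 0.30. The metallothioneins, small metal-binding proteins, had 4 of 9 members 2-fold higher and none lower, with MT2A at 2.74, MT1X at 2.70 and MT4 at -0.40; their median was 0.94, and close sequences may share signal between them. Drug-metabolising enzymes and transporters went both ways, with 6 members 2-fold higher and 3 lower among 16 above the filter. CYP1A1, a target of the aryl hydrocarbon receptor, was 3.46 higher and CYP2B6 stood at -5.89. The median over all 24 measured members of the list was 0.61, above the central 95%, which ran from -0.18 to 0.21.

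Genes of the ATF4 response, which make and import amino acids under stress, were lower in the knockout array. Of 22 members above the filter, 8 were at least 2-fold lower and none higher. PHGDH, the entry enzyme of serine synthesis, stood at -2.55 and CHAC1, which degrades glutathione, at -2.45, while TRIB3 was the highest member at 0.92. The median of -0.57 lay below all 10000 random lists. Endoplasmic reticulum chaperones had a median of -0.18 at percentile 2.43 of random lists, just under the bound of 2.5, with DNAJB9 at -1.23, EDEM1 at 0.91 and 1 of 18 members 2-fold lower. The percentile was 2.92 when all transcript clusters of a gene were averaged, which ends that call. Oncofetal and progenitor genes of the liver had a median of -0.35, below the central 95% from -0.17 to 0.26. Of their 19 members, 2 (AFP and DLK1) were 2-fold lower and 3 were 2-fold higher, among them CD44, a hyaluronan receptor, at 4.07.

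Lipid synthesis genes were higher by smaller amounts. Of 19 cholesterol synthesis genes, 4 were 2-fold higher and none 2-fold lower, with a median of 0.53. INSIG1, a sterol-responsive regulator, was 1.51 higher and the sterol reductase gene TM7SF2 1.30 higher, while LSS, on chromosome 21, stood at -0.31. Fatty acid synthesis genes had a median of 0.52, with 4 of 15 above the filter 2-fold higher. ACSS2, which makes acetyl-CoA from acetate, was 1.86 higher, PNPLA3 1.82 higher and GPAM was at -0.30. Genes of hypoxia and glycolysis had a median of 0.63, with 7 of 21 above the filter 2-fold higher and 1 lower. The oxygen sensor gene EGLN3 was 2.67 higher and the glycolytic enzyme gene PFKP 2.21 higher, whereas HK2 was at -1.39. Each of these medians lay above the central 95% of random lists.

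Antigen presentation genes were higher as well, with 6 of 12 above the filter at least 2-fold higher and none 2-fold lower. Their median over all 18 measured members was 0.66. HLA-DMA, which loads peptides on class II molecules, was 2.82 higher and TAPBP, of the class I loading complex, 1.52 higher, while the class II chaperone gene CD74 stood at -0.84. NF-kB and inflammatory genes had a median of 0.45 over all 22 measured members. Of the 13 above the filter, 1 was past 2-fold, the inhibitor gene NFKBIA at 1.13. IL32 was 0.99 higher and LTB stood at -0.19. Interferon-stimulated genes had a median of 0.07, inside the range of random lists, but the 10 of 26 members above the filter had a median of 0.67, above it at percentile 99.86, with IFITM3 at 1.46, IFITM1 at 1.10 and USP18 at -0.49. Of 9 integrin genes above the filter, 5 were 2-fold higher, with ITGA2 at 1.98, ITGA3 at 1.87 and ITGB4 at -0.13. The parental value of ITGA3, 3.19, lay under the filter. The integrin median over all 18 measured members, 0.33, lay above the central 95% from -0.21 to 0.20.

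The design also bears on chemokine and vessel-forming signals, since SOX4 in liver cancer has been studied for its link to CXCL12, a chemokine that draws cells bearing CXCR4. CXCL12 was lower in the knockout array, at 10.28 against 11.26, a difference of -0.98 or 1.98-fold. It passed 2-fold after quantile normalization, at -1.05, and just passed it after removal of the level trend. Both of its receptors were higher, CXCR4 at 12.94 against 10.69, or 4.76-fold, and ACKR3 at 9.13 against 5.97, or 8.94-fold. Chemokines as a list had a median of 0.19 at percentile 97.14, inside the central 95%, with CXCL8 at 0.90. The call is not firm, since the list passed the bound after quantile normalization (percentile 98.16), after removal of the level trend (97.52), with all clusters of a gene averaged (97.72), with no matching on level (97.61) and over the 12 members above the filter, whose median was 0.35 (97.74). It did not pass with the mean of members, with centred arrays or without chromosome 21 and blocks of neighbouring genes. Chemokine receptors had a median of -0.00, with only 3 of 17 above the filter. Angiogenic ligands and inhibitors had a median of 0.06, with 6 of 19 above the filter 2-fold higher and 2 lower; TIMP1 was highest and ADAMTS1, an inhibitor of vessel growth on chromosome 21, stood at -2.18. Over the members above the filter that median was 0.33, above the random range at percentile 97.68. Semaphorins, plexins and neuropilins, which guide axons and vessels, had 9 members 2-fold higher and 2 lower with a median of -0.08. SEMA3E was 3.29 higher, SEMA4B 2.16 higher and SEMA6A was at -1.58. Genes reported elsewhere as SOX4 targets had a median of -0.14, inside the random range; TEAD2, a partner of YAP, was at -2.69, whereas SEMA3C was 1.45 higher and EGFR 1.08 higher.

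Other lists of signalling and cell state had medians inside the central 95% of random lists when all measured members were used. Mesenchymal genes had a median of -0.09, with FBN1 2.57 higher, the repressor ZEB1 2.51 higher and SNAI2 at -1.20, and epithelial adhesion genes had a median of -0.16, with the splicing factor ESRP1 at -2.94, JUP at -0.80 and KRT7 at 0.70. Extracellular matrix genes had a median of 0.10 with EFEMP1 at 2.97, COL6A1 at 2.87 and FBLN1 at -1.41, and matrix proteases and their inhibitors a median of -0.03. Wnt target genes had a median of 0.13, with BMP4 at 1.24 and MYC at -0.53, and Wnt ligands, receptors and antagonists 0.02, with FZD6 at 2.14, WNT2B at 2.03 and LRP6 at -0.99. The LRP6 value came from 1 of its 8 clusters, labelled unmapped. WNT2B at 3.35 and COL6A1 at 3.25 in the parental array, and SNAI2 at 4.39 in the knockout array, lay under the level filter. TGF-beta and BMP targets had a median of -0.06, with SMAD6 at -1.81, HAMP at -1.34 and JUNB at 1.23. YAP and TEAD targets had a median of 0.17, with IGFBP3 at 3.03, MYOF at 2.68 and ANKRD1 at -0.71. Notch pathway genes had a median of -0.17, with DLL4 at -1.47 and MAML2 at 1.27, and Hedgehog pathway genes -0.02, with CDON at 0.47, PTCH1 at 0.26 and SMO at -0.22. The insulin-like growth factor axis had a median of -0.09 with IGFBP1 at 3.52 and IRS2 at -1.21, and receptor tyrosine kinases a median of -0.11 with MERTK at -1.23 and ERBB4 at -1.16.

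Liver-specific and housekeeping lists also lay inside that range. Hepatocyte plasma proteins had a median of -0.07, with VTN at 1.35 and APOA1 at -1.17. Liver transcription factors had a median of -0.21 at percentile 2.71, with CEBPA at -0.89 and PPARA at 0.87. The list lay below the random range with no matching on level, at percentile 2.40, and without chromosome 21 and blocks of neighbouring genes, at 2.29. Bile acid genes had a median of -0.01, in spite of BAAT at 5.34, with AKR1D1 at -1.13. Acute-phase proteins had a median of -0.19, with CP, the copper carrier ceruloplasmin, at 1.68. Genes of S phase and of G2 and mitosis had medians of -0.02 and 0.02, and none of their 26 members each was 2-fold apart; E2F1 was at 0.88, CDT1 at 0.71, CCNE2 at -0.57, AURKB at 0.53, KIF20A at 0.50 and CENPF at -0.43. Apoptosis regulators had a median of 0.14, with the death ligand TNFSF10 at 4.22 and BCL2L11 at -1.28. Heat-shock genes had a median of -0.12, with HSPH1 at -0.90 and HSPB1 at 0.59. Cytosolic ribosomal proteins had a median of -0.00, with RPS6 at -0.80 and RPL19 at 0.46, and ribosome biogenesis genes -0.11, with WDR12 at -0.85 and NHP2 at 0.60. Oxidative phosphorylation subunits had a median of 0.16, with CYC1 at 1.09 and ATP5PO, on chromosome 21, at -0.85. Replication-dependent histones had a median of 0.18, with H2BC5 at 1.47, H4C1 at 1.21 and H2AC8 at -0.28. Common reference genes had a median of 0.29 at percentile 97.17, with 12 of 13 members above 0. HPRT1 was at 0.86, ACTB at 0.79 and TBP, the only member below 0, at -0.74.

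Of the 46 gene lists, 9 lay above the central 95% of random lists, 3 below and 34 inside, where randomly drawn genes would put 2.3 outside. That number assumes genes that vary independently, which members of a list need not do. It may also be too low because random lists held non-coding genes, while protein-coding genes were more often 2-fold apart. How far the calls exceed chance is thus not known. In 13 gene or marker lists the median and the mean differed in sign, and none of them was called by its median; the semaphorin list had a mean of 0.31, chemokine receptors 0.27, bile acid genes 0.26, the insulin-like growth factor axis 0.17, mesenchymal genes 0.08, TGF-beta and BMP targets 0.08, S-phase genes 0.05, matrix proteases 0.04, hepatocyte plasma proteins 0.01 and SOX genes -0.04. The means of the semaphorin list and of chemokine receptors lay above those of random lists, at percentiles 97.53 and 98.73. The other lists of this kind were fibroblast and stellate markers with a mean of 0.32, leukocyte markers with 0.20 and cervical line markers with 0.40. Some of the 34 lists were called when only members above the filter were used. Wnt ligands, receptors and antagonists then had a median of 0.55 (percentile 99.72) and extracellular matrix genes 0.45 (percentile 99.36), both above the random range, and receptor tyrosine kinases -0.29 (percentile 1.44), below it. That filter goes by the higher array, so some members pass it through 1 array alone; with the filter on the mean of both arrays, added after seeing the data, the Wnt median was 0.45 over 10 members and that of extracellular matrix genes 0.43 over 14, both still above. Common reference genes stayed at 0.29 and passed the bound with the former filter, at percentile 97.70, but not with the latter. With no matching on level they passed it at percentile 99.03. With the mean of members, Wnt target genes at 0.40, YAP and TEAD targets at 0.44, Wnt ligands and receptors at 0.23, extracellular matrix genes at 0.38 and angiogenic genes at 0.35 lay above, and epithelial adhesion genes at -0.24 below. Markers of other cell types were inside the random range by their medians over all measured members. These were -0.08 for endothelial, -0.15 for fibroblast and stellate, -0.04 for leukocyte, 0.11 for cholangiocyte, 0.04 for erythroid and -0.05 for kidney line markers, and 4 measured markers of a cervical line had a median of -0.10, too few to set against random lists. The 5 cholangiocyte markers above the filter had a median of 0.64, above the random range at percentile 98.96. Single markers were higher, and were picked after their values were seen. LUM, a matrix proteoglycan, was 4.79 higher, SPP1 2.52 higher, LYZ 2.25 higher, SFN 2.08 higher and CD68 1.09 higher.

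**Figure D2:**
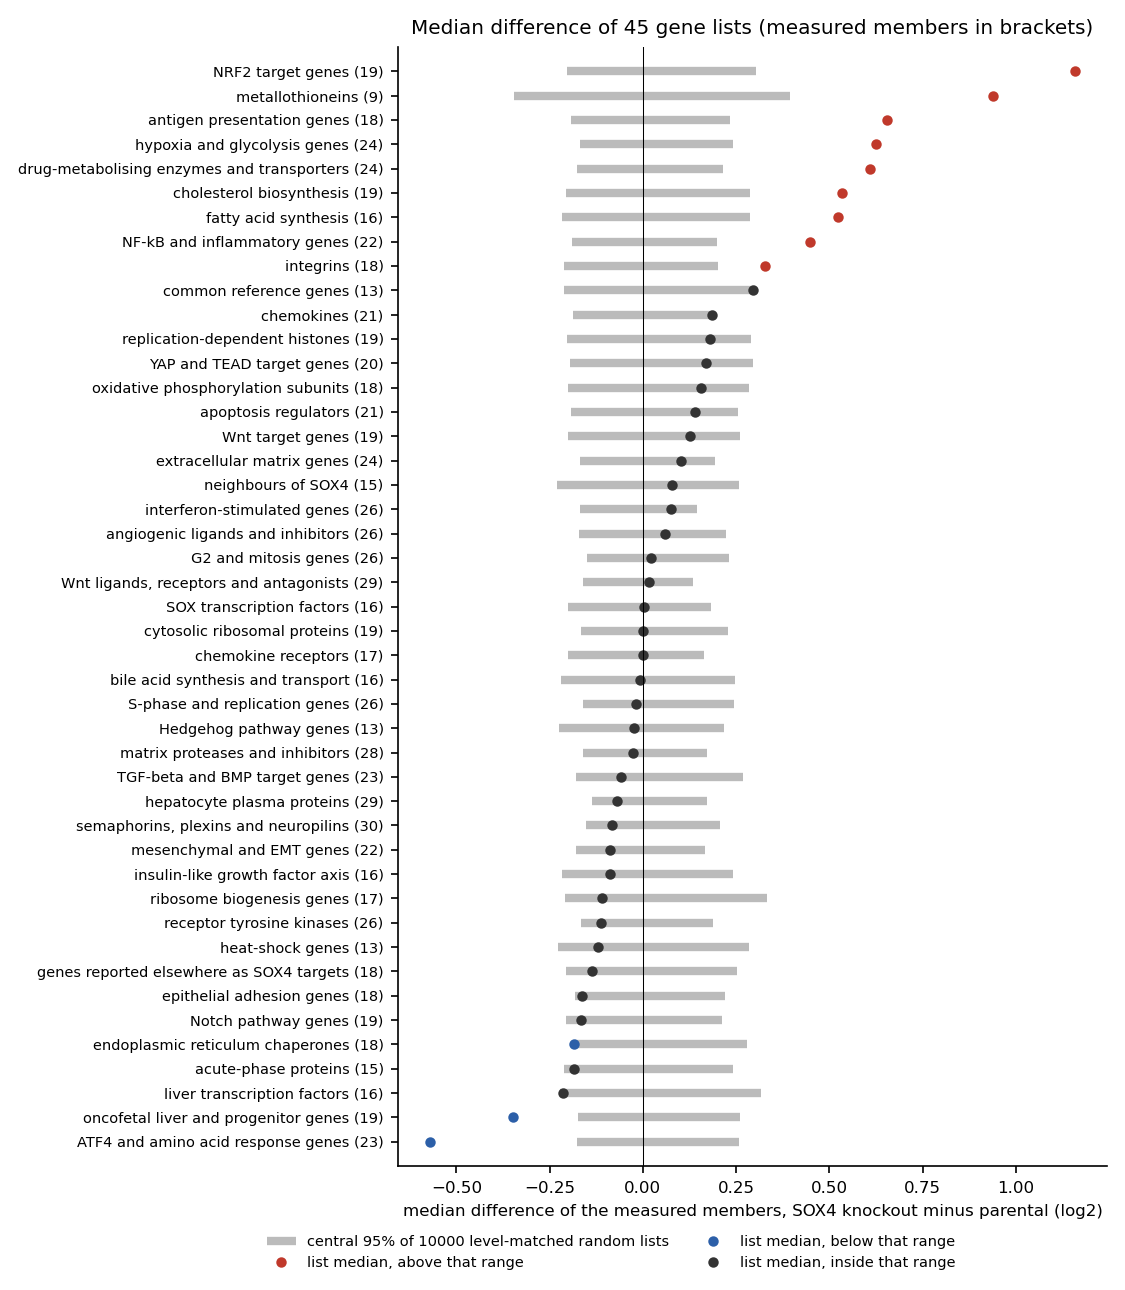
Points give the median difference, SOX4 knockout minus parental in log2, of the measured members of each of 45 gene lists, and grey bars the central 95% of 10000 random lists matched on level. The 9 red points lie above their bars, led by NRF2 targets at 1.16, and the 3 blue points below, with ATF4 and amino acid response genes at -0.57.

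Along the genome, the genes of chromosome 21 were lower together in the knockout array. Their median difference was -0.48 over 149 genes above the filter, of which 79.9% lay below 0, 32 were at least 2-fold lower and 3 at least 2-fold higher. CBR1, FAM3B, ADAMTS1 and ATP5PO were among the lower genes, and COL6A1 was 2.87 higher. Chromosomes 5, 8, 13 and 19 also had medians below the central 95% of random sets, at -0.02, -0.04, -0.16 and -0.12. Chromosomes 1, 11, 20 and 22 lay above, at 0.13, 0.27, 0.15 and 0.13. The value for chromosome 22 was 0.01 and inside the range when all genes with a position were used. Runs of 25 neighbouring genes formed 9 blocks beyond those of 100 shuffled orders, 2 higher and 7 lower, which held 3.30% of 13313 ordered genes and 7.36% of the 2-fold genes among them. The blocks were picked by these same differences, so a larger share of 2-fold genes in them follows from that choice and is no separate support. The blocks that were higher lay on chromosome 11, from SPINDOC to PPP2R5B and from EFEMP2 to LINC01488, with medians of 0.68 and 0.67. A lower block on chromosome 9 ran from DDX11L5 to IFT74 and held CER1 and RPS6, with a median of -0.68. Lower blocks on chromosome 2 ran from ACTR3 to WDR33 at -0.72 and from SMPD4BP to STAM2 at -0.50; CXCR4, in the latter, was higher against that trend. On chromosome 19 lower blocks ran from ARMC6 to DPY19L3, from LRFN3 to YIF1B and from CCDC106 to ZNF550, with medians of -0.71, -0.43 and -0.49. Zinc finger genes named ZNF made up 36 of 72, 28 of 43 and 25 of 32 genes of these blocks, and 0 in the blocks elsewhere. The chromosome 19 blocks thus do not by themselves show a shift of their regions. The block of chromosome 21 ran from HSPA13 to SIM2 at -0.54.

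**Figure D3:**
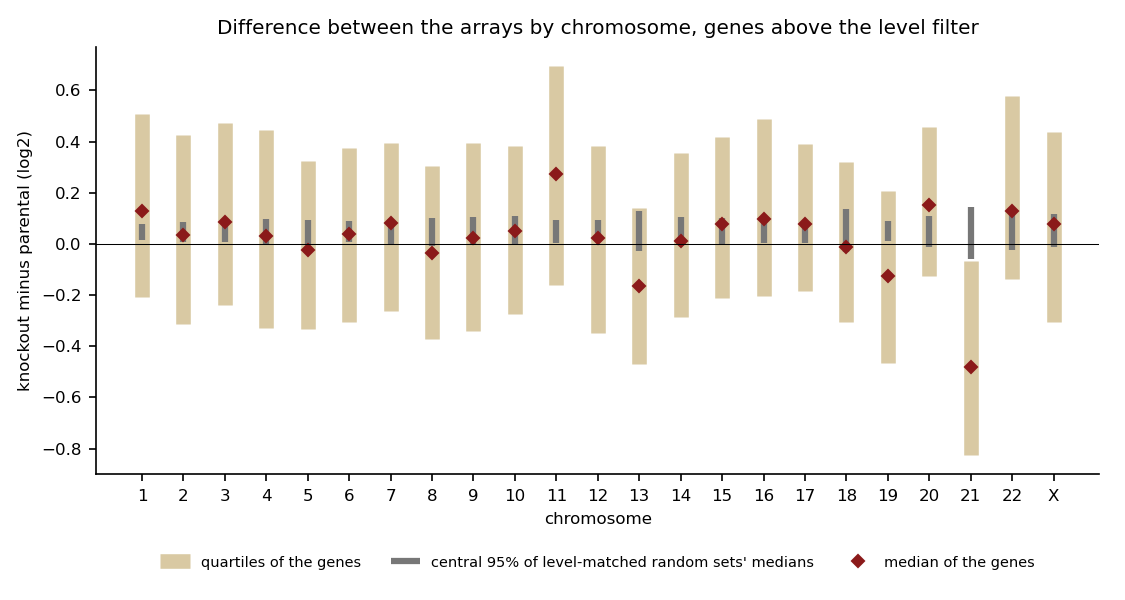
Diamonds give the median difference, SOX4 knockout minus parental in log2, of the genes above the level filter on each autosome and X; wide bars span the quartiles of the genes and narrow bars the central 95% of medians of level-matched random sets. Chromosome 21 is lowest at -0.48 and chromosome 11 highest at 0.27.

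Zinc finger genes named ZNF were lower on chromosome 19 and elsewhere, a grouping made after the values were seen. The 225 on chromosome 19 had a median of -0.61 and 51 were 2-fold lower with none 2-fold higher, and the 207 on other chromosomes had a median of -0.28, with 23 at least 2-fold lower and 6 higher. The 662 other genes of chromosome 19 had a median of 0.00. Non-coding RNA classes were summarised apart. Small nucleolar and Cajal body RNAs had a median of -0.26 over 176 genes above the filter, with 9 at least 2-fold lower and 2 higher; SNORD9 stood at -1.83 and SNORA51 at 1.73. MicroRNA symbols had a median of -0.12 over 460 genes, with MIR4324 at -3.39 and MIR548AI at 2.93. Among 299 antisense, intronic and overlapping transcripts the median was -0.04, with ZFPM2-AS1 at 4.31 against 11.12 and CDR1-AS at 15.05 against 10.84. Other small RNAs, LINC symbols and LOC symbols had medians of -0.03, 0.02 and -0.03.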

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

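The tests on chromosome 21 and on NRF2 targets below were chosen only after the results were seen, while those on the count of 2-fold genes were written beforehand.

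Signal outside the named genes also differed between the arrays. Among 25361 transcript clusters with no gene name above the filter, 901 were at least 2-fold higher in the knockout array and 1078 at least 2-fold lower. Among 704 clusters with several names, 45 were higher and 22 lower. The report's comparisons use neither kind, and no replicate array bears on them.

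The genes at least 2-fold apart numbered 1705. Noise of dim probes would leave few among bright genes, yet the share in the brightest tertile was 0.944 times that in the dimmest, 8.39% against 8.89%, which argues against it as the whole cause. An offset that depends on level was small beside 2-fold, since medians of genes grouped by level ran from -0.04 to 0.10. The count after removal of the loess trend, 1706, is no separate test. Removing so small a trend from values already normalized could hardly change it. A difference in copy number between the lines stays open for part of these genes. Of 2-fold genes, 16.1% had shifted neighbours against 10.1% of all genes. That excess of 5.94 percentage points lies between the bounds set beforehand. In a count added after seeing the data, 1062 higher and 513 lower genes remained without chromosome 21 and blocks. Shifts of those regions thus do not account for most of the 2-fold genes. Neighbours counted as shifted when the median of the nearest 24 lay below -0.28 or above 0.39, outside the central 99% of shuffled orders. Both shares thus exceed what shuffled orders give. Loss of SOX4, puromycin, selection of a subclone and the single hybridisation remain untested alternatives that the design confounds.

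The genes of chromosome 21 were lower in the knockout array. They were lower than genes of like level, since the random sets were matched on mean level. Once the loess trend was removed the median remained -0.47 and below random sets. That step is no separate test of a level-dependent offset, because matching had already taken out an offset shared by genes of like level. The trend was also small, with medians of genes grouped by level from -0.04 to 0.10. Fewer copies of the chromosome in the knockout line is a candidate explanation that cannot be told apart from others here. The share of genes below 0 was 79.9%, a little short of the bound of 80% set for it, while the next highest chromosome, 13, had 63.5%. No measure of DNA was analysed here.

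The NRF2 targets were higher in the knockout array. Signal shared between aldo-keto reductase paralogs is argued against as the whole cause, since the 15 members left without AKR symbols had a median of 0.98, still above random lists. The members' 168 neighbouring genes had a median of 0.17, well under the list median of 1.16. That argues against extra copies as the whole cause over the regions pooled. The neighbours' median was not set against random sets, though it exceeded the 0.04 of all genes above the filter. A gain at some of the regions stays open. Less KEAP1 transcript, the adaptor that marks NRF2 for degradation, is argued against by KEAP1 itself, which was 0.64 higher, while NFE2L2, the gene of NRF2, was 0.34 higher. Among the members, SLC7A11 at -1.13 and HMOX1 at -0.11 were not higher. Besides extra copies and KEAP1 transcript, no biological explanation was tested, and loss of SOX4, puromycin and selection of cells stay open.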

How the results depend on the processing

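The results without chromosome 21 and blocks, those with the filter on the mean of both arrays and the NRF2 list without aldo-keto reductases were chosen only after the results were seen. No called result changed its sign under the alternatives run. No paired analysis was possible because there was 1 array per genotype. Leaving out a replicate and another background correction were not run, for want of a second array and of scanner files. Of the named genes, 551 values under alternatives kept their side of 2-fold and 5 passed it newly; of list medians 422 kept their call, 32 were called newly and 3 were lost; of chromosome medians 110 kept it, 3 were called newly and 2 were lost. Many of these values could hardly change. Centring moves every difference by the same amount, and averaging clusters alters only genes with more than 1 cluster. The deposited values were also already normalized between arrays, so the totals are a weak check. The 3 lost list calls were those of endoplasmic reticulum chaperones, at -0.18 with the mean of all clusters of a gene, -0.18 with no matching on level and -0.13 with the mean of members. Genes at least 2-fold higher and lower numbered 643 and 332 with the filter at the 75th percentile, which tests fewer genes. At 1.5-fold they numbered 2634 and 1904, and at 4-fold 226 and 80, as the thresholds themselves imply. Lists above random lists numbered 15 when members above the filter alone were used, 14 with members whose mean lay above it and 17 with the mean of members, against 9; the cause was not tested. Without chromosome 21 and blocks, 1062 genes were higher and 513 lower. Scaling moved the median of all genes by at most 0.02. Signal over background could not be judged without detection calls, which limits what can be said of the dim genes.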

Other observations

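The families of symbols described here were grouped, and their tests chosen, only after the results were seen. Of 132 families of at least 10 protein-coding genes sharing their leading letters, 8 lay above and 4 below the central 99% of random families. Randomly drawn genes would put 1.32 outside, a number that assumes genes that vary independently. The random families were drawn from all genes above the filter, not from protein-coding genes alone, so that number may be too low. UDP-glycosyltransferases with UGT symbols, many of which conjugate drugs and steroids, had a median of 1.32 over 11 genes, with 8 at least 2-fold higher. The lowest members were UGT3A2 at -0.53 and UGT3A1 at 0.14. UGT2B15 was 4.64 higher and UGT2B17 3.54 higher, though these paralogs are close in sequence and may share signal to an unknown extent. Annexins, which bind membranes and calcium, had a median of 0.64, with ANXA1 4.73 higher and ANXA6 at -1.30, the only members of 12 past 2-fold. Tetraspanins had a median of 0.62 over 14 genes, 4 of them at least 2-fold higher and 1 lower, with TSPAN15 2.01 higher, TSPAN6 just over 2-fold lower and TSPAN13 at -0.93. S100A11 and S100A6, calcium-binding proteins, were 4.81 and 3.91 higher, and S100A14 stood at -1.34; their family, symbols with the letter S before a digit, had a median of 0.66 over 11 genes. The 60 genes with the letter H before a digit, histones among them, had a median of 0.26, above the random range, with H2BC4 at 1.48 and H3-3B at -0.30, whereas the fixed list of replication-dependent histones lay inside its range. The TM, B and TMEM symbols had medians of 0.49, 0.42 and 0.19.

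Families lower in the knockout array included the ZNF genes, counted here over protein-coding genes alone, with a median of -0.43 over 401 genes of which 70 were 2-fold lower and 5 higher. The clustered protocadherins PCDHB had a median of -0.69 over 12 genes, with 1 of them 2-fold lower, PCDHB2 at -1.27, and with PCDHB10 at -0.98 and PCDHB16 at 0.20. The 12 ZSCAN zinc finger genes had a median of -0.47, with 1 2-fold lower, ZSCAN16 at -1.36. The 10 bitter taste receptor genes had a median of -0.43, with 2 at least 2-fold lower and TAS2R10 at -1.40.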
